A study of Nothobranchius furzeri with 8 samples.

How the data were processed

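Small RNA libraries were made from total RNA of the brain of 8 male killifish samples with the TruSeq small RNA kit, per the labels' protocols, 4 at an age of 6 weeks and 4 at 26 weeks. The kit ligates adapters to both ends of small RNAs, and ligation and amplification favour some sequences over others, so levels of different miRNAs are less comparable than levels of 1 miRNA across libraries. Per the submitters' processing notes, the tools were bcl2fastq 1.8.4, Trimmomatic 0.36, BWA 0.7.12-r1039 and SAMtools 1.3.1-9. The values deposited by the authors are whole-number counts per miRNA family or predicted miRNA for each library, not normalised. The genome build, the annotation, the counting tool, the mismatch and length settings and the treatment of reads that map to several loci are not given in the sources used here. Features are named per family and without arms, and how paralogues and arms were combined is not given. No change of 1 paralogue or of arm use within a feature can therefore be seen. The comparison of arm use fixed before the data were examined could not be run. Some features may share reads, such as mir-132 and mir-132b, mir-96 and mir-96a, or mir-122 and a joint feature with mir-3591, and their separate values are uncertain. The reference table used here lists genes of 1 assembly and was not used, since it was not matched to miRNA features, so no coordinates are given.

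Libraries were grouped by the age label, and the column of each library was matched to its sample by the title. The numbers I to IV in the titles named the replicates. No 2 libraries of a group were near copies: the chi-square per degree of freedom between counts of 2 libraries of an age, over features with enough counts, was at least 131. Totals ran from 2992917 to 5715409 counts per library. Without molecular identifiers in the protocol given, counts are not independent molecules, so depth bounds counting error only. Features that the expression filter left out numbered 112 and held 0.00948% of the counts.

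Counts were analysed in R 4.3.3. The test of age was edgeR 4.0.16's quasi-likelihood test on all 8 libraries with TMM factors, filterByExpr and no covariate, two-sided, with Benjamini-Hochberg adjustment over the tested features (173 named families and 39 predicted miRNAs) and a threshold of 0.05. Fold changes are 26 weeks over 6 weeks, and CPM is the usual library-size-scaled count after TMM scaling. SE is an approximate standard error of the log2 fold change. For edgeR it is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Log2 CPM used a prior count of 2. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, where a list had at least 3 tested members (9 of 24 lists), with camera at an estimated correlation and with fry as alternatives. Lists were fixed before the data were examined, by family number: let-7, miR-29, miR-15/16, miR-17-92 and paralogous clusters, miR-23/24/27, miR-26 and miR-101, miR-30, miR-34 with miR-449, miR-10/99/100/125, miR-181, miR-130 with miR-301 and miR-454, miR-221/222, neuron-enriched, oligodendrocyte, microglia and leucocyte, erythroid, endothelial and mural, muscle, liver and gut, sensory organ, choroid plexus and pigment epithelium, epithelial, neuroendocrine and miR-430. The lists match names only, so lin-4, the family name that covers miR-125, and mir-8, that of the miR-200 family, did not enter them. The joint feature of mir-122a and mir-3591 did not enter the liver and gut list either. Library measures were compared with exact two-sided permutation tests of the difference of means over all assignments of 4 against 4, whose smallest p is 0.0286.

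The rule for named miRNAs, also fixed before the data were examined, had 3 parts: called miRNAs whose libraries did not overlap between ages, up to 12 per direction with the largest fold change (12 higher and 8 lower), the 5 most abundant families, and for each list the 2 members with the smallest p, or up to 4 where more were called. It named 56 miRNAs.

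The numbers I to IV were checked for pairing before the fits were compared. Deviations from the age means correlated between libraries of the same number by 0.287 to 0.528 across features, the highest value between different numbers was 0.234, and 8 of 8 libraries correlated best with the library of their own number. By the limit of 0.1 for every pair, fixed beforehand, the numbers pair the libraries, and the labels do not say what a number stands for. The fit with the number as a block is therefore given beside results it changes.

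Alternatives were RLE, upper-quartile and total-count scaling, TMM without the 5 most abundant families, no filter, a minimum of 10 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, robust quasi-likelihood, the block, leaving out each library, an adjusted p of 0.1 and a 1.5-fold minimum. Fits without both libraries I, with the log2 total as a covariate (alone and with the block) and on counts thinned to 2992917 per library were added after the data were seen. The code was tested on 20 simulated tables of the comparison between ages with 40 changed features among 315 simulated. It recovered 41.8% of 2-fold and 15.5% of 1.5-fold changes, 6.91% of its calls were false, and unchanged tables gave 0 calls by edgeR. With simulated effects of the library number (SD 0.4 on the log2 scale), recovery of 2-fold changes was 29.1% with the block and 0.250% without it, and that of 1.5-fold changes was 3.15% and 0%. The simulated spread came from the fit without the block and already held differences between numbers, so these effects were added on top. These recoveries therefore do not give the power of the fits to the real counts. Figures were drawn with matplotlib 3.10.9.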

Results

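Small RNA was sequenced from the brain of male turquoise killifish (Nothobranchius furzeri), a short-lived annual fish, of the strain MZM-04/10p. The 8 libraries formed 2 age groups, with 4 libraries at 6 weeks and 4 at 26 weeks. Titles of the older libraries carry the number 22, whereas their age label and the series design give 26 weeks, and the age label was followed. Each library was described by counts for 324 features, of which 235 were named miRNA families and 89 were predicted miRNAs with names beginning with pred_. The libraries at 6 weeks held 2992917, 3252550, 4151620 and 3092056 counts for the numbers I to IV, and those at 26 weeks held 3347810, 5715409, 5357039 and 4542396. The labels do not say that the libraries came from separate fish, so the p-values measure the spread between these samples, which could in part be technical. Values are given per family, and the table of counts gave no arms and no genomic positions.

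The miRNA profile of the brain was dominated by a few families at both ages. The 5 most abundant, mir-181, let-7, mir-9, mir-26 and mir-128, took 63.2 ± 1.01% of the counts at 6 weeks and 62.3 ± 0.911% at 26 weeks (SD, n = 4 each, exact two-sided permutation p = 0.229). Within them, mir-181 took 29.2 ± 2.03% of the counts at 6 weeks and 24.9 ± 2.11% at 26 weeks (n = 4 each, exact permutation p = 0.0571). The share of let-7, the family linked to developmental timing and differentiation, was 14.2 ± 2.18% at 6 weeks and 18.3 ± 2.93% at 26 weeks (n = 4 each, exact permutation p = 0.0857). The share of mir-26 was 5.62 ± 0.310% at 6 weeks and 7.25 ± 0.339% at 26 weeks, and the 4 older libraries all lay above the 4 younger ones (exact permutation p = 0.0286, the smallest that 4 against 4 can give, unadjusted). Shares of mir-9 were 7.49 ± 0.599% and 6.70 ± 1.63% (exact permutation p = 0.4), and those of mir-128, a neuronal family, were 6.68 ± 0.410% and 5.14 ± 0.950% (exact permutation p = 0.0571, n = 4 each). The number of features with at least 1 count was 291 ± 2.94 at 6 weeks and 285 ± 6.08 at 26 weeks (n = 4 each, exact permutation p = 0.143). The effective number of miRNAs, the exponential of the Shannon entropy of the shares, was 17.6 ± 0.735 and 17.96 ± 1.09 (n = 4 each, exact permutation p = 0.6). Its difference of 0.380 turned to -0.105 without the 26-week library I and to -2.31 without mir-181 (exact permutation p = 0.0857). Mean totals were 3372290 ± 530455 counts at 6 weeks and 4740660 ± 1050300 at 26 weeks (n = 4 each, exact permutation p = 0.0571), so depth and age could not be fully separated. After Benjamini-Hochberg adjustment over the 4 library measures (total, features with a count, share of the top 5, effective number), the exact permutation p-values were 0.229, 0.286, 0.305 and 0.6. Without the 26-week library numbered I, the difference in totals was 1832660 counts and that in features with a count was -8.67, each with an exact permutation p of 0.0286, unadjusted.

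The comparison between the ages asked which miRNAs differed in abundance between the younger and the older brain. Of the features tested, 173 named families and 39 predicted miRNAs, 22 were higher and 8 were lower at 26 weeks. Among well-expressed families, mir-29, a regulator of collagen and other extracellular matrix transcripts, rose 3.23-fold, from 643 ± 61.2 to 2078 ± 280.0 CPM (counts relative to the scaled library size, mean ± SD, n = 4 per age). The family mir-101, known to target the histone methyltransferase Ezh2, rose 2.97-fold, from 3661 ± 345 to 10866 ± 2128 CPM (n = 4 per age). The oligodendrocyte families mir-338 and mir-219, which promote the maturation of myelinating glia, rose 2.40-fold and 2.62-fold. The falls among well-expressed families were smaller than these 4 rises, with mir-216, mir-217, mir-299 and mir-454 between 0.569-fold and 0.617-fold of their level at 6 weeks.

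By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold changes were 1.69 ± 0.15 for mir-29 (SE, adjusted p = 2.14e-04), 1.26 ± 0.12 for mir-338 (adjusted p = 2.79e-04) and 1.57 ± 0.16 for mir-101 (adjusted p = 3.00e-04). In the same edgeR test with Benjamini-Hochberg adjustment, mir-219 rose by 1.39 ± 0.28 (adjusted p = 0.0126), mir-451 by 1.15 ± 0.17 (adjusted p = 0.00326) and mir-430 by 1.72 ± 0.38 (adjusted p = 0.0167). The family mir-430, which clears maternal transcripts in the fish embryo, was scarce at both ages, at 5.06 ± 0.673 CPM at 6 weeks and 16.7 ± 7.29 CPM at 26 weeks (n = 4 each). Rises near 2-fold were found for mir-337 (log2 1.18 ± 0.22), mir-202 (1.13 ± 0.23), mir-187 (1.13 ± 0.21) and mir-592 (1.09 ± 0.20). Of these, mir-187 went from 1075 ± 62.8 to 2347 ± 736 CPM and mir-337 from 748 ± 52.1 to 1698 ± 541 CPM (n = 4 each), whereas mir-202 and mir-592 stayed below 20 CPM on average. The 22 higher features also included mir-22 (log2 0.74 ± 0.13) and mir-455 (0.66 ± 0.15), the only called features outside the fixed naming rule, named after their values were seen. Among the 8 lower features, mir-216 fell by 0.81 ± 0.16 on the log2 scale, from 1851 ± 186 to 1053 ± 196 CPM (n = 4 each). Its neighbour in the vertebrate cluster, mir-217, fell by 0.73 ± 0.18, mir-299 fell by 0.77 ± 0.19 and mir-454 fell by 0.70 ± 0.16. The others were of low abundance: pred_159 fell by 1.34 ± 0.33, mir-186 fell by 1.43 ± 0.37, pred_640 fell by 1.10 ± 0.23 and mir-2985 fell by 1.46 ± 0.41. The last of these held 3.48 ± 0.777 CPM at 6 weeks and 1.27 ± 0.741 CPM at 26 weeks (n = 4 each). Each of the 8 falls was lost without at least 1 single library, with edgeR Benjamini-Hochberg adjusted p up to 0.124 and the same direction throughout; for mir-216 this was the 6-week library IV alone (adjusted p = 0.0528), for mir-217 and mir-454 it was 4 libraries each, and for mir-186 and mir-2985 7 each. Predicted miRNAs made up 39 of the tested features, of which 0 rose and 2 fell by edgeR with Benjamini-Hochberg adjustment.

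**Figure D1:**
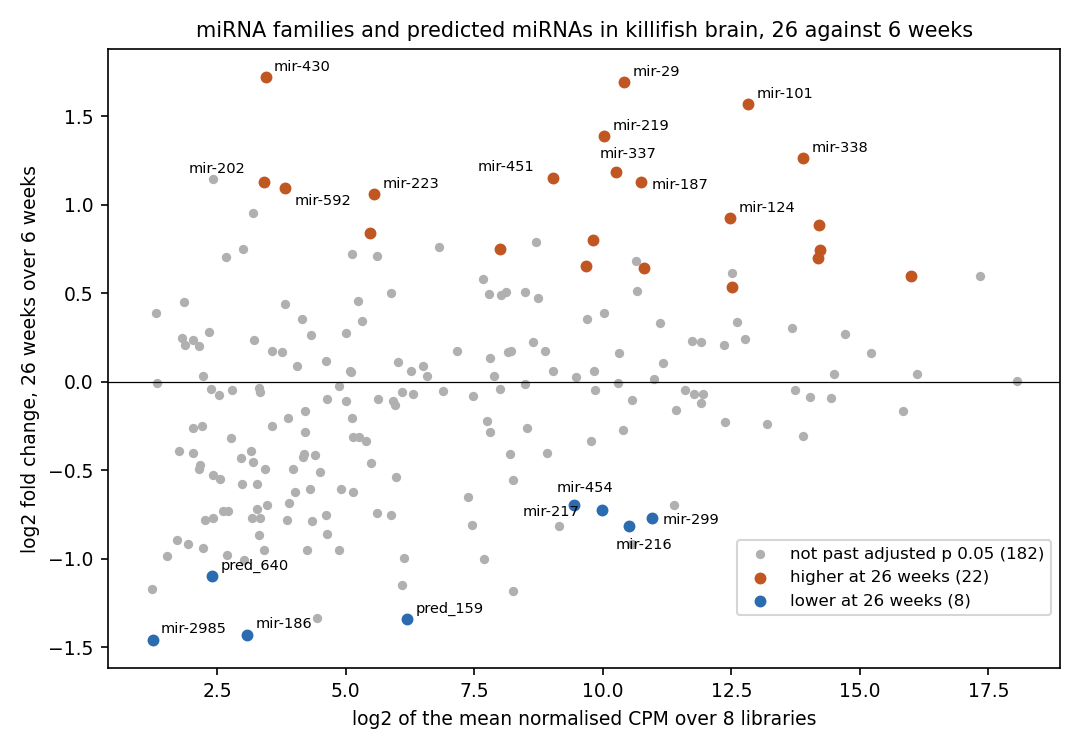
Each point is a tested feature, with the log2 of its mean normalised CPM over the 8 libraries on the x axis and the log2 fold change, 26 weeks over 6 weeks, on the y axis. Orange points mark the 22 features higher and blue points the 8 lower at 26 weeks (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), and mir-29, mir-101 and mir-338 combine large rises with high abundance.

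In the 30 called features the libraries of the 2 ages did not overlap, so each necessarily changed in its direction in 4 of 4 pairs of libraries with the same number. Across all tested features 46, or 21.7%, had groups that did not overlap, against 2.86% by chance. The count of features with an unadjusted edgeR p under 0.05 was 62. With the library number as a block, a fit fixed before the data were examined, 59 features were called (35 higher, 24 lower), including all 30. Without both libraries numbered I, a setting chosen after the data were seen, 50 were called (30 higher, 20 lower), of which 29 were among the 30, and without the 26-week library I alone 47 were called. With the log2 total count as a covariate, also chosen afterwards, mir-29, mir-101, mir-219 and mir-338 remained past the threshold, the other 26 did not, and all 30 kept their direction. Scaling mattered for the balance of the calls: the split was 15 higher and 12 lower with total counts alone and 15 and 11 with upper-quartile factors, while the median log2 change of all tested features moved from -0.06 to -0.29 and -0.24. Each of these scalings kept 23 of the 30 calls, and all 22 higher and all 8 lower features kept their direction.

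**Figure D2:**
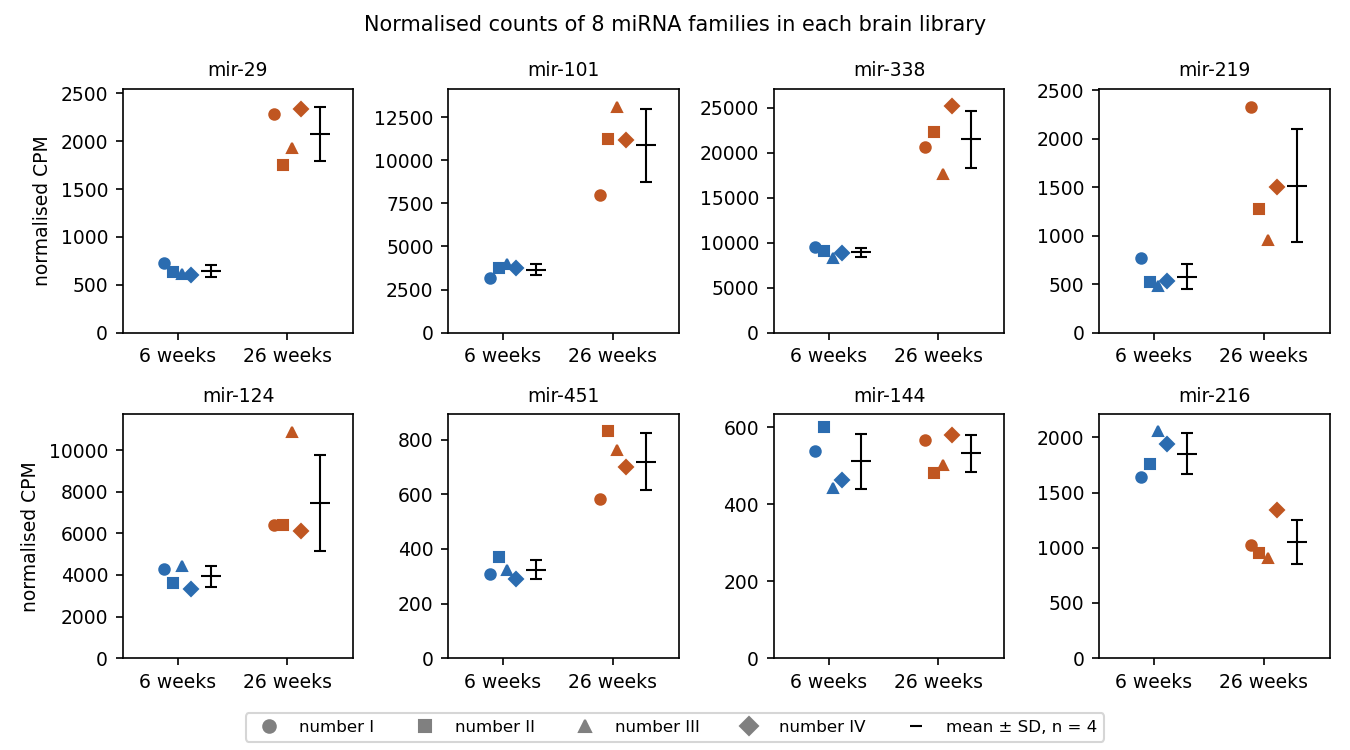
Normalised CPM on the y axis, from 0, for 8 miRNA families in each library at 6 weeks (blue) and 26 weeks (orange), with 1 symbol per library number and the mean ± SD (n = 4) beside them. The ages are separate for mir-29, mir-101, mir-338, mir-219, mir-124, mir-451 and mir-216, and they overlap for mir-144.

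Among 13 tested members of the neuron-enriched list, 4 rose and 0 fell, and the same 4 passed when adjusted over the list alone. The 4 were mir-124, the main neuronal miRNA of vertebrates (log2 0.92 ± 0.21), mir-132, which responds to neuronal activity (0.70 ± 0.14), mir-132b (0.54 ± 0.12) and mir-139 (0.64 ± 0.15). In CPM, mir-132 went from 14210 ± 1591 to 23099 ± 3787 (n = 4 each), and mir-132 and mir-132b may share reads. With upper-quartile factors 4 of these 4 lost their call (edgeR, Benjamini-Hochberg adjusted p = 0.0503 for mir-124, 0.0545 for mir-132, 0.0961 for mir-132b and 0.0541 for mir-139), as did mir-124 and mir-139 with total counts (adjusted p = 0.0576 and 0.0715). Members that did not pass included mir-9 (0.05 ± 0.12), mir-128 (-0.17 ± 0.09) and mir-7 (0.06 ± 0.44). As a list, the neuron-enriched miRNAs did not pass limma's camera test (Benjamini-Hochberg adjusted p = 0.214, and adjusted p = 0.563 with an estimated correlation), but passed it without the expression filter (adjusted p = 0.0462). By fry from limma the adjusted p was 0.0575 for a shift one way on balance and 0.00128 for changes in either direction (Benjamini-Hochberg). Both members of the oligodendrocyte list rose: mir-338 went from 8954 ± 514 to 21493 ± 3147 CPM and mir-219 from 578 ± 131 to 1515 ± 584 CPM (n = 4 each). The call of mir-219 was lost with total counts (edgeR, Benjamini-Hochberg adjusted p = 0.0579), and the list was too short for a list test.

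Of 6 miRNAs of microglia and leucocytes, 3 rose and 0 fell, over all features and adjusted over the list alone. These were mir-223 of myeloid cells (log2 1.06 ± 0.25), mir-150 of lymphocytes (0.84 ± 0.23) and mir-142 of haematopoietic cells (0.75 ± 0.17). The call of mir-150 was lost without the 6-week library II, III or IV (edgeR, Benjamini-Hochberg adjusted p up to 0.0716) and with upper-quartile factors (adjusted p = 0.0980), and with total counts 3 of these 3 calls were lost (adjusted p = 0.0702 for mir-223, 0.144 for mir-150 and 0.0715 for mir-142). The list did not pass camera (limma, Benjamini-Hochberg adjusted p = 0.117, and adjusted p = 0.393 with an estimated correlation). It passed camera without the expression filter (adjusted p = 0.0177) and without the 26-week library III (adjusted p = 0.0416). By fry, which tests whether members move one way on balance, the adjusted p was 0.0247, with 0.00221 for changes in either direction. Of the erythroid pair, which is made from 1 transcript, mir-451 rose from 323 ± 35.2 to 719 ± 105 CPM, whereas mir-144 was at 511 ± 72.5 and 533 ± 48.5 CPM (log2 0.06 ± 0.16, n = 4 each). Among vessel wall miRNAs, 0 of 3 passed over all features and 2 of 3 when adjusted over the list alone, mir-126 (0.61 ± 0.24) and mir-145 (0.58 ± 0.18). With the library number as a block, both passed over all features (edgeR, Benjamini-Hochberg adjusted p = 0.0241 and 0.0287), and mir-145 also passed with RLE factors (adjusted p = 0.0369), DESeq2 (3.04e-04) and limma-voom (0.0441). The endothelial and mural list had a camera adjusted p of 0.176, an adjusted p of 0.393 with an estimated correlation and a fry adjusted p of 0.0247 (limma, Benjamini-Hochberg).

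Markers of tissue that could be carried over in dissection showed 0 calls over all features. The muscle list had 3 tested members (mir-133 at 0.16 ± 0.14, mir-499 at -0.25 ± 0.30), and the liver and gut list had 3 (mir-194 at 0.44 ± 0.25, mir-122 at -0.41 ± 0.33). In both lists camera and fry differed in sign, and the muscle list's median (-0.10) and mean (-0.06) went against camera's direction. The joint feature of mir-122a and mir-3591, which the liver and gut list missed by its name, was at -0.86 ± 0.45. Its adjusted p was 0.228, and 0.0469 with the number as a block (edgeR, Benjamini-Hochberg). None of the 5 sensory organ miRNAs passed, with mir-96a at -0.95 ± 0.35 and mir-96 at -0.77 ± 0.53, though mir-96a was lower with the number as a block (edgeR, Benjamini-Hochberg adjusted p = 0.0407). Of the epithelial miRNAs, mir-205 was at -0.81 ± 0.35 (blocked edgeR, Benjamini-Hochberg adjusted p = 0.0407, and 0.163 unblocked) and mir-203 at -0.13 ± 0.19. For choroid plexus and pigment epithelium, mir-204 was at 0.34 ± 0.19. In the neuroendocrine list, mir-375 ranged widely between libraries of 1 age, from 19.2 to 722 CPM at 6 weeks and from 23.5 to 504 CPM at 26 weeks, and its change was -1.19 ± 1.03. Without both libraries numbered I, a setting chosen after the data were seen, it fell by 2.78 on the log2 scale (edgeR, Benjamini-Hochberg adjusted p = 0.0137, with 0.0137 to 0.803 over the alternatives). The library numbered I held the most mir-7 and mir-1 at each age.

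**Figure D3:**
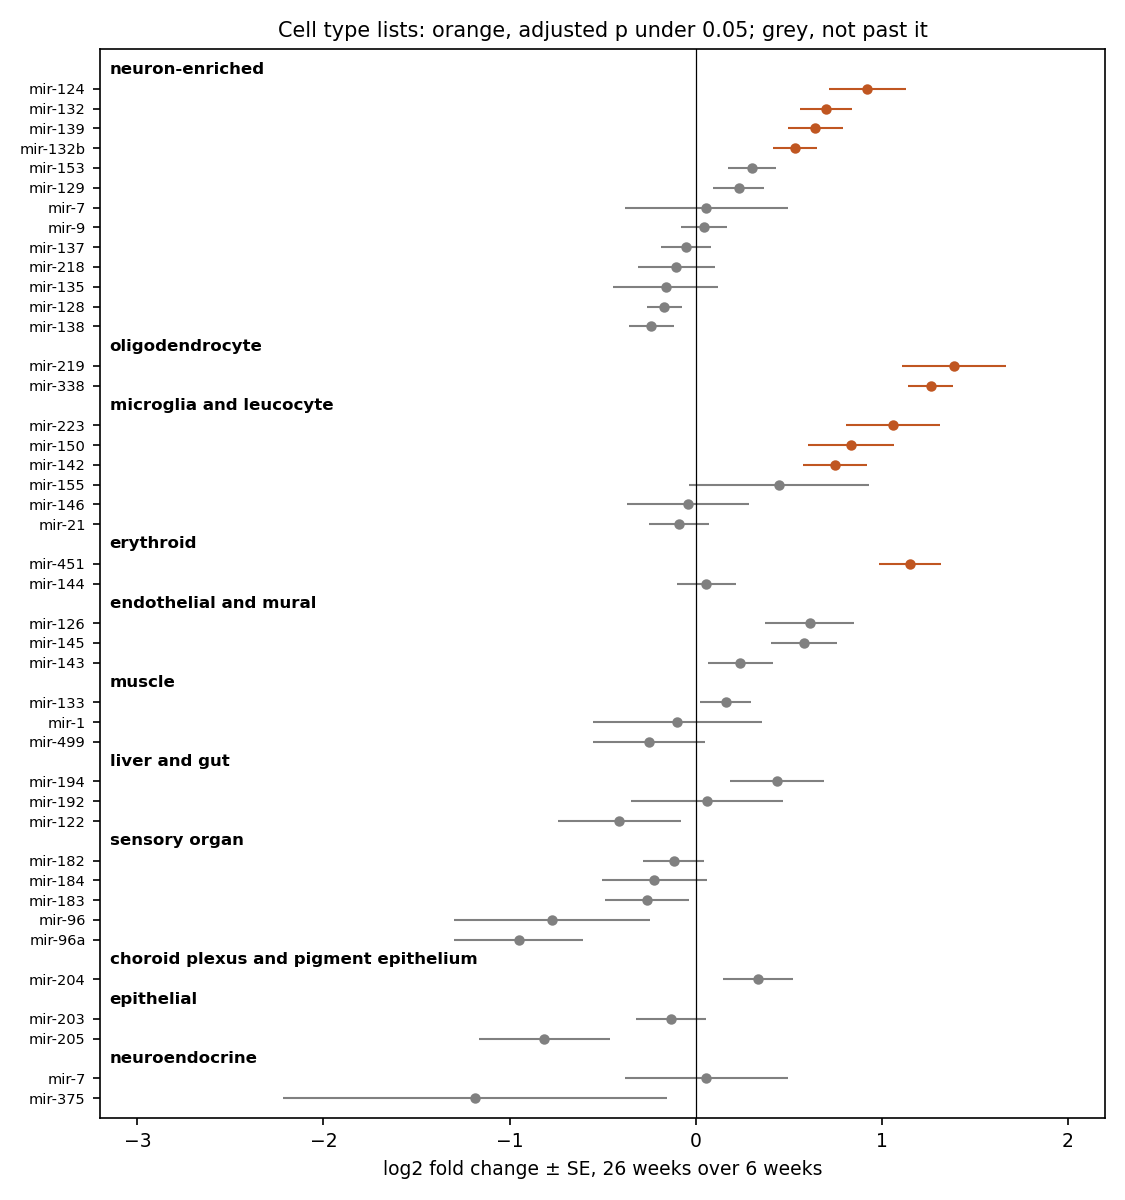
Log2 fold change, 26 weeks over 6 weeks, ± SE on the x axis for each tested member of 11 cell type lists (n = 4 per age), with orange for an edgeR Benjamini-Hochberg adjusted p under 0.05 and grey otherwise. Members of the oligodendrocyte, leucocyte, neuron-enriched and erythroid lists passed upwards, and 0 members passed downwards; the signs of mir-7, mir-9, mir-129, mir-133, mir-144 and mir-192 changed with total-count or upper-quartile scaling.

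Among the family lists, the miR-23/24/27 cluster had 2 of 3 members higher, mir-27 (log2 0.89 ± 0.17) and mir-23 (0.80 ± 0.14), and 3 of 3 when adjusted over the list alone or, over all features, with the number as a block (mir-24, edgeR, Benjamini-Hochberg adjusted p = 0.0407). It was the only 1 of the 9 lists tested to pass camera (limma, Benjamini-Hochberg adjusted p = 0.0410), and this was lost with an estimated correlation (adjusted p = 0.255). It was also lost without both libraries numbered I (adjusted p = 0.0538) and without any 1 of 5 libraries, the 6-week II, III and IV and the 26-week I and II (camera adjusted p from 0.0503 to 0.0610). The abundant mir-27 went from 13353 ± 1885 to 24682 ± 4866 CPM (n = 4 each). Both members of the miR-26 and miR-101 list rose, mir-26 by 0.60 ± 0.13 on the log2 scale, a call lost with upper-quartile factors (edgeR, Benjamini-Hochberg adjusted p = 0.0622). The let-7 family was at 0.60 ± 0.20 (edgeR, Benjamini-Hochberg adjusted p = 0.0889), and passed with the number as a block (adjusted p = 0.0125). Its list holds 1 member, so adjustment over the list alone leaves its unadjusted edgeR p of 0.0164. The list of miR-130, miR-301 and miR-454 had 1 of 3 members lower, mir-454, with mir-301 at -0.33 ± 0.15, which passed with total counts (-0.57, edgeR, Benjamini-Hochberg adjusted p = 0.0129). The lists miR-15/16 (mir-16 at -0.23 ± 0.11, mir-15 at -0.05 ± 0.14), miR-17-92 and paralogues (mir-25 at 0.33 ± 0.14, mir-92 at -0.31 ± 0.15) and miR-34 with miR-449 (mir-34 at 0.22 ± 0.35, mir-449 at 0.17 ± 0.27) held 0 called members. Of these, mir-16 was lower with upper-quartile factors (-0.40, edgeR, Benjamini-Hochberg adjusted p = 0.0360) and with total counts (-0.45, adjusted p = 0.0241). Single families without a call were mir-30 (-0.05 ± 0.10), mir-10 (0.04 ± 0.35), mir-181 (0.00 ± 0.12) and mir-221 (0.16 ± 0.13). The miR-29 and miR-430 lists held 1 member each, and both rose. Adjusted p from camera for the other 8 tested lists ran from 0.117 to 0.978 (limma, Benjamini-Hochberg). The signs of mir-7, mir-9, mir-10, mir-130, mir-133, mir-144, mir-181, mir-192 and mir-221 changed with total-count and upper-quartile scaling, as did those of mir-129, mir-449 and of the neuron-enriched and liver and gut medians with total counts.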

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

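The outlying values here come from a comparison fixed before the data were examined, as do the tests of other splits and of scaling; the tests of thinned counts, of the total count as a covariate, of blood, of neurons and of the libraries numbered I were chosen after the results were seen. Among 120 groups of 4 libraries, 5 had a value whose gap to the nearest other exceeded Dixon's critical value for groups of that size, and chance gives about 1 in 20, or 6.

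The family mir-124 had a log2 CPM of 13.41 in the 26-week library III against 12.58 to 12.65 in the other 26-week libraries. For mir-299, the 6-week library II was at 11.12 and the others at 11.33 to 11.36. For mir-454, the 26-week library IV was at 9.40 and the others at 8.88 to 8.95. For mir-150, the 6-week library I was at 5.48 and the others at 4.78 to 4.89. For mir-375, the 6-week library I was at 4.30 and the others at 8.80 to 9.50.

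The 22 rises and 8 falls with age were set against depth, scaling and a state of the library that follows its total. The real split gave 30 calls, which 1 of the 35 splits reached. The highest of the others was 28, for the 4 deepest against the 4 shallowest libraries (3 calls shared with age). The 35 splits treat the libraries as exchangeable, whereas the numbers pair them. Among the 8 splits that part all 4 pairs, the highest of the others was 0. Since 8 splits are too few for a share under 0.05, the splits cannot exclude chance. Thinning to 2992917 counts kept 29 of the 30 calls, which argues against the unequal number of counts alone as the whole cause. Thinning keeps the proportions of a library on average, so it cannot remove a bias in them that goes with depth. The lowest median change of the 22, which were chosen as risen with TMM, over 4 other scalings was 0.76 against 0.99. That scaling, total counts, moved the median of all tested features from -0.06 to -0.29, a shift smaller than the rises. This argues against scaling by a few abundant families as their whole cause, though total counts and upper-quartile factors each kept 23 of the 30 calls. With the log2 total as a covariate mir-29, mir-101, mir-219 and mir-338 passed over all tested features. The lowest was at 1.22 ± 0.15 (edgeR, Benjamini-Hochberg adjusted p of the 4 at most 0.00161). This argues against a state that follows the total as their whole cause. The 4 were set apart from the other 26 by this same fit, so the loss of the 26 calls is no separate result. With the block as well, on 2 residual degrees of freedom, 0 features passed (24 at an unadjusted edgeR p under 0.05). There the 4 stayed at 1.05 ± 0.23 or more and the 30 kept their direction at a median of 0.811. For the other 26 the median change was 0.859 with the covariate and 0.862 without, but 26 of 26 calls were lost (both the change and its SE fell for 3, as for mir-132 from 0.70 ± 0.14 to 0.36 ± 0.10, the change fell and the SE rose for 15, and both rose for 8), and since the total rose with age, age and such a state cannot be told apart for them.

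In the fit with the number as a block, the real split gave 59 calls and the highest of the others 0, where only 8 splits part all 4 pairs, too few for a share under 0.05. For lists, 7 of the 35 splits gave at least the real count of 1 and the highest of the others was 2, so chance cannot be excluded for the miR-23/24/27 result.

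The rises of mir-338, mir-219, mir-223, mir-150, mir-142 and mir-451 were set against a lower share of neurons and against more blood left in the older brains. A lower share of neurons would raise all other cell types alike. The mean log2 CPM of the oligodendrocyte list rose over that of the endothelial and mural list by 0.83 ± 0.13 within pairs of 1 number (SE over 4 pairs, 4 of 4 above 0). Unpaired, the SE was 0.31 and the exact permutation p was 0.0571. Over the leucocyte list it rose by 0.82 ± 0.12 (4 of 4), or ± 0.14 unpaired (exact permutation p = 0.0286). The oligodendrocyte list thus rose more than the leucocyte list, also unpaired. Both oligodendrocyte rises were known when these lists were compared, so this is not independent support against a lower share of neurons as the whole cause. The 4 neuronal rises, which a lower share of neurons would push down, stayed between 0.37 and 0.77 with upper-quartile factors, though their calls were then lost. These 4 were picked for rising, and the other 9 of 13 members did not pass. The median of the neuron-enriched list was 0.06, and -0.11 with total counts, so the list does not decide the question. Blood should bring both erythroid miRNAs, and the log2 ratio of mir-451 to mir-144 rose by 1.08 ± 0.18 (SE, n = 4 per age, exact permutation p = 0.0286), mir-451 rising by 396 ± 55.3 CPM while mir-144 moved by 21.1 ± 43.6. The proportion of the pair in killifish red cells was not measured here, so more blood may still have added mir-451 with little mir-144, and a change in cell makeup with age stays open and untested.

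Features high in the libraries numbered I at both ages were compared with low depth, muscle and shared handling. In both libraries 21 features lay at least 1 log2 unit above the mean of the others of that age (31 and 33 singly, 4.83 by independent overlap), against 0, 0 and 1 for the numbers II, III and IV; 10 were predicted, 0 were called with age (3 lower with the block, mir-158, pred_118 and pred_638), and mir-716, mir-7, mir-158 and pred_484 added most. After all libraries were thinned to 1 total, 20 of the 21 still lay that high. Thinning keeps proportions on average and left the 6-week library I, the smallest, unchanged, so this could not test low depth. The 33 chosen at 26 weeks alone were higher in the 6-week library I than in II and IV, of nearly its total. The medians were 0.94 and 1.15 (29 and 30 of 33 above 0). The SE of the mean over features was 0.25 for each, though features are not independent. This argues against low depth in the 6-week library I, but it compares single libraries. In muscle carried over mir-1 would lead, yet it took at most 1.68% of the added CPM. Of the 24 ways to pair the libraries, only the numbering as given had so high a mean correlation. Samples with one number may therefore have been handled together. The correlation was taken over all features past the filter, these 21 included, so it is not separate support. No biological explanation other than carried-over muscle was tested.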

How the results depend on the processing

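Fits without both libraries numbered I, with the log2 total count as a covariate (alone or with the block) and on thinned counts were chosen after the data were seen, and the other alternatives before. The count of 30 changed miRNAs stayed within 1.5 times under RLE (31), upper-quartile (26) and total-count (27) scaling, TMM without the 5 most abundant families (34), no filter (26), the 10 CPM minimum (27), DESeq2 (40), limma-voom (31), robust quasi-likelihood (30), thinning (32), an adjusted p of 0.1 (41) and a 1.5-fold minimum (29). It went to 59 with the replicate number as a block, to 50 without both libraries numbered I, to 4 with the covariate and to 0 with block and covariate together (24 at an unadjusted p under 0.05 by edgeR, 2 residual degrees of freedom). Leaving out 1 library gave 23 to 47, with 47 without the 26-week library I. The falls among these ran from 2, without the 6-week library II or IV, to 18, without the 26-week library I. Without the filter the falls numbered 3. Of the 28 called miRNAs that the text names by rule, 0 reversed in any setting and 19 kept their call without each single library. The calls of mir-2985, mir-186 and mir-299 were lost in 11, 9 and 7 settings. The block ended no call; among lists and miRNAs named by rule it changed no call other than those given with a blocked value. Total counts and upper-quartile factors each kept 23 of the 30 calls. TMM factors averaged 1.08 ± 0.0622 at 6 weeks and 0.931 ± 0.122 at 26 weeks (SD, n = 4 each, exact two-sided permutation p = 0.114). Scaling by total counts leaves these factors out, which lowered the changes of all features nearly alike, with a median of -0.29 instead of -0.06. The balance of 22 rises and 8 falls thus depends on these factors. For the other settings the cause of the changes was not tested.

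The count of 1 list past the threshold went to 0 with an estimated correlation, with RLE factors, with the 10 CPM minimum and without both libraries I, to 3 with directional fry, 2 with mixed fry and 3 with no filter, and to 0 to 2 when 1 library was left out. Differences in total counts ran from 1043460 to 1832660 and in features with a count from -8.67 to -4 over single libraries left out. The effective number differed by 0.380, by -0.105 to 0.730 over single libraries left out, and by -2.31 without mir-181, the most abundant family.

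Signs reversed only for named miRNAs and lists without a call. With total counts the TMM factors were left out, and for the other settings the cause was not tested. With upper-quartile factors the log2 fold changes were -0.16 for mir-181, -0.13 for mir-9, -0.12 for mir-10, -0.0081 for mir-221, -0.12 for mir-144, -0.0098 for mir-133 and -0.092 for mir-7. With total counts only they were -0.23 for mir-181, -0.16 for mir-9, -0.068 for mir-449, -0.23 for mir-10, -0.058 for mir-221, -0.16 for mir-144, -0.044 for mir-133 and -0.11 for mir-7, with list medians of -0.11 for neuron-enriched and -0.20 for liver and gut. Without the filter mir-15 was at 0.056, mir-30 at 0.048, and the miR-17-92 and muscle medians at 0.060 and 0.033. With the 10 CPM minimum mir-181 was at -0.063, mir-9 at -0.020, mir-10 at -0.029 and the liver and gut median at -0.0086. DESeq2 gave 0.021 for mir-15 and 0.013 for mir-30, and limma-voom -0.0057 for mir-181 and -0.078 for mir-10. The block gave -0.0073 for mir-181, -0.082 for mir-10 and -0.17 for the liver and gut median. Without both libraries I, mir-9 was at -0.013, mir-15 at 0.013, mir-7 at -0.010, and the miR-17-92 and neuron-enriched medians at 0.065 and -0.010. With the covariate mir-181 was at -0.22, mir-449 at -0.12, mir-10 at -0.92, mir-221 at -0.027, mir-499 at 0.074, mir-96 at 0.20 and mir-204 at -0.035. Leaving out 1 library gave ranges of -0.024 to 0.18 for mir-181, -0.0059 to 0.24 for mir-9, -0.074 to 0.076 for mir-15, -0.072 to 0.092 for mir-30, -0.023 to 0.44 for mir-449, -0.24 to 0.32 for mir-10, -0.32 to 0.011 for mir-499, -0.18 to 0.047 for mir-203 and -0.44 to 0.52 for mir-7. List medians ran from -0.10 to 0.18 for miR-17-92, -0.0059 to 0.33 for neuron-enriched, -0.29 to 0.22 for muscle and -0.40 to 0.29 for liver and gut.

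The comparison of arm use and its 4 alternatives were not run, since the counts are per family. At this depth 112 features with 0.00948% of the counts were left out by the filter and not tested. A simulated 2-fold change was recovered in 41.8% of cases over all abundances, so a feature without a call is not shown to be the same at both ages.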

Other observations

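The tests in this part other than that of the spread within each age were chosen after the results were seen. A further group not described above is that of family names known from other organisms. A list of names made for this check matched 28 such features, 9 named for plant, 3 for viral, 13 for nematode and 3 for insect families. The list was not complete and left out names such as mir-1027, mir-42 and mir-315, so its counts and shares cover the listed names only. Of the 28, 22 were tested and 0 were called by edgeR with Benjamini-Hochberg adjustment. Names known only from other vertebrates were not checked, so this does not show that every called name belongs to the killifish. With the number as a block 2 of the 28 were higher (mir-46 and mir-48) and 3 lower (mir-158, mir-408 and mir-BHRF1). The 28 features took 0.833 ± 0.0360% of the counts at 6 weeks and 0.685 ± 0.107% at 26 weeks (SD, n = 4 each, exact two-sided permutation p = 0.0571). The most abundant of them was mir-BART15, named for a viral family. Among nematode names, mir-83, which shares its seed with mir-29, was at 0.09 ± 0.31 where mir-29 rose by 1.69 ± 0.15, and mir-48, a sister of let-7, was at 0.51 ± 0.22 where let-7 was at 0.60 ± 0.20, and both passed with the block (edgeR, Benjamini-Hochberg adjusted p = 0.0406 and 0.0125, higher in 4 of 4 pairs).

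Predicted miRNAs took 0.780 ± 0.247% of the counts at 6 weeks and 0.433 ± 0.173% at 26 weeks (SD, n = 4 each, exact two-sided permutation p = 0.0857). Of the 39 tested, 25 had a log2 fold change below 0, and with the number as a block 1 was higher and 9 were lower.

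A hypothesis that older brains vary more from fish to fish was set against the spread between libraries within each age. That spread could in part be technical, so the test cannot tell fish from handling. The median log2 ratio of the SD at 26 weeks to that at 6 weeks was 0.491, and 70.3% of miRNAs had the larger SD at 26 weeks. Of 70 assignments of the centred values, a share of 0.0714 had as high a ratio (exact permutation, one-sided), so a larger spread at 26 weeks may be present but was not shown. The assignments did not take the pairing of libraries by number into account. Without the libraries I the ratio was 0.414.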
